A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

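The study measured gene expression by RNA sequencing in fission yeast, Schizosaccharomyces pombe, with 1 library of wild-type cells and 1 library of cells in which ppr10 had been deleted. Both came from cultures in logarithmic growth. Per the labels' protocols, total RNA was taken with Trizol and made into libraries with a NEBNext Ultra RNA kit for Illumina sequencing; whether the libraries kept the strand is not given in the sources used here. The submitters' processing notes list Bowtie2 2.2.3 and TopHat2 2.0.12 and the genome build ASM294v2, while the series' design text names BWA with ANOVA, and TopHat with Cufflinks. Which of these made the values, and the annotation release, the strand setting and any filter on reads, are not given in the sources used here.

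A single deposited table held both libraries. Per the file headers, it gives for each gene a length, a count of uniquely mapped reads per library, an RPKM value (reads scaled to the length of the gene and the size of the library) and a coverage score. Each library was assigned to its group from the deposited column names and the labels. The deposited counts are whole numbers, and the total in each column's header equals the sum of that column. The RPKM values were made by the authors from those reads, the listed length and the column total: recomputing them from the same table gave a largest absolute difference of 4.99e-07. Because 5075 of the 5076 lengths are multiples of 3, they are taken here as coding lengths without untranslated regions. The deposited coverage score carries a percent sign and describes how much of the length reads cover, but it exceeds 100 in 7 genes, so it was used only to describe ppr10. A dash in the table was read as 0.

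The gene lists, the rule for naming genes and the rules of size were fixed before the data were examined. They assumed RPKM values, and RPKM remained the measure of size when read counts were found beside them. The counts served for intervals of counting error. With 1 library per group no count model and no p-value was used. For each gene the difference was log2((deletion RPKM + 1)/(wild-type RPKM + 1)), with a pseudocount of 1 RPKM, which makes the differences of weakly expressed genes smaller. A gene was counted as higher or lower in the deletion library where that difference reached 2-fold, among genes with a mean RPKM of at least 1. This rule of size describes the 2 libraries, not the 2 conditions. Ratios of RPKM are given with exact (Clopper-Pearson) 95% intervals from the reads of the gene in both libraries. Reads from PCR-amplified libraries without molecular identifiers are not independent molecules, so every interval covers counting error only.

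There were 25 gene lists, written from knowledge of fission yeast. The iron lists were included because published work has linked loss of mitochondrial PPR proteins with iron genes, so they were not an independent choice. Each list was summarised by its members that were higher, lower or between, by its median log2 difference, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart where the percentile was below 2.5 or above 97.5; the percentile is a description of these libraries. Several lists share genes. A few members carry a listed symbol but have another function in this species. These are rpp1, rpp21 and rpp40 (RNase P or MRP subunits) among the cytosolic ribosomal proteins, rsm1 (RNA export) among the mitochondrial ones, par1 (a phosphatase subunit) among the mitochondrial expression factors, and trr1 (thioredoxin reductase, matched through an older symbol) and nuc1 (an RNA polymerase I subunit) among the cell death genes. Further ones are ssp1 (a kinase) among the chaperones, str3 (a siderophore transporter) in amino acid synthesis, and zip1 (a transcription factor) among the copper and zinc genes. They were kept as written and left out in an alternative. By annotated product, ccp1 (a histone disassembly chaperone) in the iron-using list and car1 (an arginase) in the phosphate and thiamine list also have another function. Both were kept in every setting.

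The rule for naming genes took ppr10, the 12 genes with the largest positive and the 12 with the largest negative difference at a mean RPKM of at least 5, and up to 4 members of each list at that level with the largest absolute difference, or up to 8 of the iron and mitochondrially encoded lists. All strain markers were named. Any other gene named in the text was chosen after its values were seen.

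Gene names, products, chromosome numbers, gene order, coding GC content and near-identical copies came from the reference assembly ASM294v3 and its annotation, a later build than that of the authors, and no coordinates are given. Of the 5076 identifiers, 5048 matched by locus tag, 1 by a synonym and 27 did not match, 9 of them mitochondrial; unmatched genes keep their identifiers. A near-identical copy was a match of at least 95% identity over at least 50% of a coding sequence, found with blastn 2.17.0. Values of genes with such a copy are uncertain, because unique reads can leave out or split the shared part. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

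The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated read counts for 4985 genes drawn at the depth of these libraries for the comparison of deletion with wild type. The 2-fold rule counted 0 of 66 genes simulated at 1.5-fold, 63 of 67 at 3-fold, 67 of 67 at 5-fold and 0 of 4774 unchanged genes. A planted list of 12 genes raised 1.5-fold came out at percentile 100, and 2 of 100 unchanged lists fell outside the central 95%. The interval covered a true ratio of 2 in 960 of 1000 simulated pairs. These simulations hold counting error and no variation between cultures.

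Alternatives changed the pseudocount, the filter on low values, the scaling of the libraries, the size of the fold, the kind of gene, the members of the lists and the matching of random lists. No library was left out. Auxotrophic and mating-type genes other than ade6, leu1, his7 and lys1 were not analysed here, and neither were glk1, mtf4, nma111, met2 and the M-factor genes of the lists.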

Results

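Gene expression was measured in 1 wild-type and 1 ppr10 deletion library of fission yeast in logarithmic growth. The gene ppr10 encodes a mitochondrial protein of the pentatricopeptide repeat family, whose members bind RNA in organelles. The submitters gave the search for a cause of cell death as the aim of the comparison. The wild-type library held 17053000 uniquely mapped reads in genes and the deletion library 16885000, each to the nearest 1000, with a median of 1543 and 1630 reads per gene. Of 5076 genes listed, 17 were at 0 reads in the wild type and 22 in the deletion. There were no biological replicates, so no difference has a check against the spread between cultures.

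The deleted gene was examined first. The library labelled as the deletion held 12 reads of ppr10 (SPBC106.19, chromosome II) against 1879 in the wild type, or 0.459 against 71.2 RPKM. The ratio was 0.00645 (95% interval 0.00333 to 0.0113), and the log2 difference was −5.63. The strain marker genes had log2 differences of −0.02 (ade6), −0.05 (his7), −0.35 (leu1) and −0.44 (lys1), a median of −0.20 at percentile 23.3 among random lists.

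In the deletion library, 8 of 12 genes for iron uptake and 9 of 20 core stress genes were higher than in the wild type, and 13 of 22 nuclear genes of the respiratory complexes were lower. The cell-surface glycoprotein gene pfl9 had the largest positive difference, at 67.8-fold the wild-type level (56.4 to 82.3), and the gene of the small heat shock protein Hsp16 stood at 17.4-fold (15.9 to 19.0). Outside that list, nde1, which encodes a mitochondrial NADH dehydrogenase, stood at 0.248 of the wild-type level (0.238 to 0.259). Over all 4986 genes with a mean RPKM of at least 1, 139 were higher by the 2-fold rule, 57 were lower, ppr10 among them, and 4790 (96.1%) lay between. The interval of the ratio lay wholly above 2 for 104 of the 139 and wholly below 0.5 for 35 of the 57. Of the 177 tested genes nearest the chromosome ends, 39 were higher or lower. The median log2 difference of all 4986 genes was 0.05, with quartiles at −0.17 and 0.26. The log2 values of the libraries correlated at 0.96 (Pearson) across genes, which are not independent replicates.

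**Figure D1:**
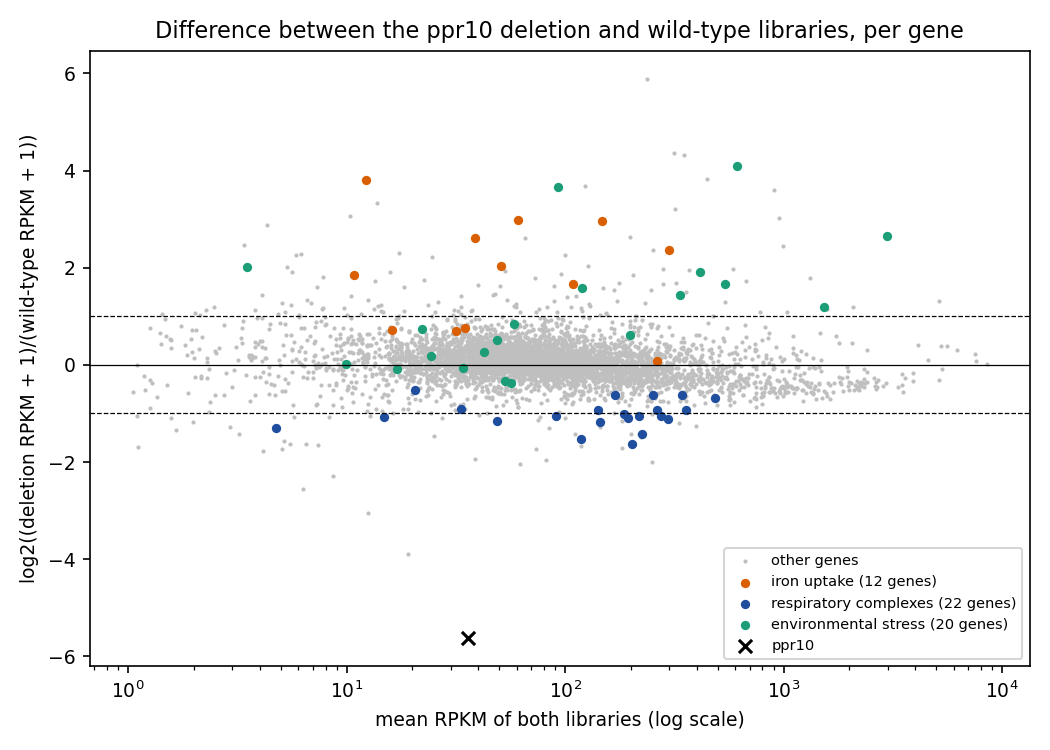
Difference between the deletion and wild-type libraries on the log2(RPKM + 1) scale (vertical axis) against the mean RPKM of both libraries (log scale), with 1 point per gene and dashed lines at the 2-fold limits. Iron uptake genes (12) all lie above 0, respiratory complex genes (22) all lie below 0, and ppr10 lies at −5.63.

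The 12 genes with the largest positive differences at a mean RPKM of at least 5 included enzymes of redox and carbon metabolism and surface proteins. Besides pfl9 (SPAC186.01, 6.87 against 466 RPKM) they were adh8, an alcohol dehydrogenase (21.4-fold, 19.5 to 23.4), the dehydrogenase gene osr1 (20.6-fold), hsp16, the But2 family gene SPAC27D7.09c (14.4-fold), and shu1, which encodes a haem acquisition protein. The ratio of shu1 was 30.7 (16.0 to 68.0), from 9 reads in the wild type and 274 in the deletion. The others were gsf2, a flocculin gene (13.6-fold, 12.8 to 14.3), the sulfiredoxin gene srx1 (13.5-fold), gpd3, which encodes glyceraldehyde-3-phosphate dehydrogenase (12.1-fold, 11.7 to 12.7), the short chain dehydrogenase gene SPCC663.08c (9.33-fold), and the uncharacterised genes SPCC338.18 (15.7-fold) and SPBPB2B2.08 (13.6-fold).

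The 12 genes with the largest negative differences after ppr10, at the same level, included several of uncharacterised product. SPCC569.03 stood at 0.0416 of the wild-type level (log2 difference −3.90), SPBC460.05 at 0.0821, the malic enzyme gene SPAC750.08c at 0.0973 and SPBC460.04c at 0.219. Besides nde1 (399.6 against 99.2 RPKM), the better expressed ones were aes1 (0.250, 0.226 to 0.276), the phosphatase gene SPAC1039.02 (0.305) and SPBPB7E8.01 (0.312). The log2 differences of SPCP20C8.02c (−2.28), SPBC1347.14c (−2.04), sro1 (−1.94) and SPCC569.01c (−1.72) are uncertain, because each has a near-identical copy; SPBC1347.14c and sro1 are copies of each other. SPBC460.05 and SPBC460.04c did not match the annotation and were not searched for copies.

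Genes for iron uptake were higher as a group. Of the 12 genes of reductive and siderophore iron uptake, which the repressor Fep1 controls, 8 were higher, none was lower and 4 lay between, and all 12 differences were positive. The median log2 difference was 1.94, at percentile 100, where 95% of random lists lay between −0.13 and 0.27. After shu1 the largest ratios were those of fio1, the ferroxidase gene (8.41, 7.59 to 9.34), its partner permease gene fip1 (7.95, 7.34 to 8.63), and the siderophore transporter genes str3 (6.58) and str1 (5.18). The ferric reductase genes frp1 and frp2 stood at 4.27 and 4.23, and sib2, of siderophore synthesis, at 3.20.

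Iron regulators did not stand apart as a list. Of 8, 2 were higher and 6 lay between, with a median of 0.08 at percentile 61.5. The 2 were php4, the repressor subunit of the CCAAT-binding complex that acts when iron is scarce (2.32-fold, 2.13 to 2.53), and php2, a DNA-binding subunit of that complex (2.11-fold, 1.86 to 2.40). The log2 difference of fep1 was 0.36 and that of php5 −0.16, and those of tup12, php3, grx4 and tup11 were no larger than 0.08 in either direction.

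Of 21 genes listed as iron-using or iron-storing and repressed by Php4, none was higher, 3 were lower and 18 lay between. Among the 18, ccp1 (log2 difference −0.31) is annotated as a CENP-A histone disassembly chaperone. The median of the 21 was −0.48 at percentile 0. The 3 were rip1, the Rieske iron-sulphur protein of complex III (0.323, 0.302 to 0.345), pcl1, a vacuolar iron transporter (0.372, 0.349 to 0.396), and tim18, listed under its older name sdh4 (0.496, 0.460 to 0.536). Log2 differences of cyc1 (−0.93), glt1 (−0.86), lys2 (−0.73), sdh1 (−0.69) and leu2 (−0.64) did not reach the limit. This list shares 6 genes with the respiratory list and 6 with the TCA cycle list. Without the former it did not stand apart: of the remaining 15 genes only pcl1 was lower, and the median was −0.24 at percentile 3.64.

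**Figure D2:**
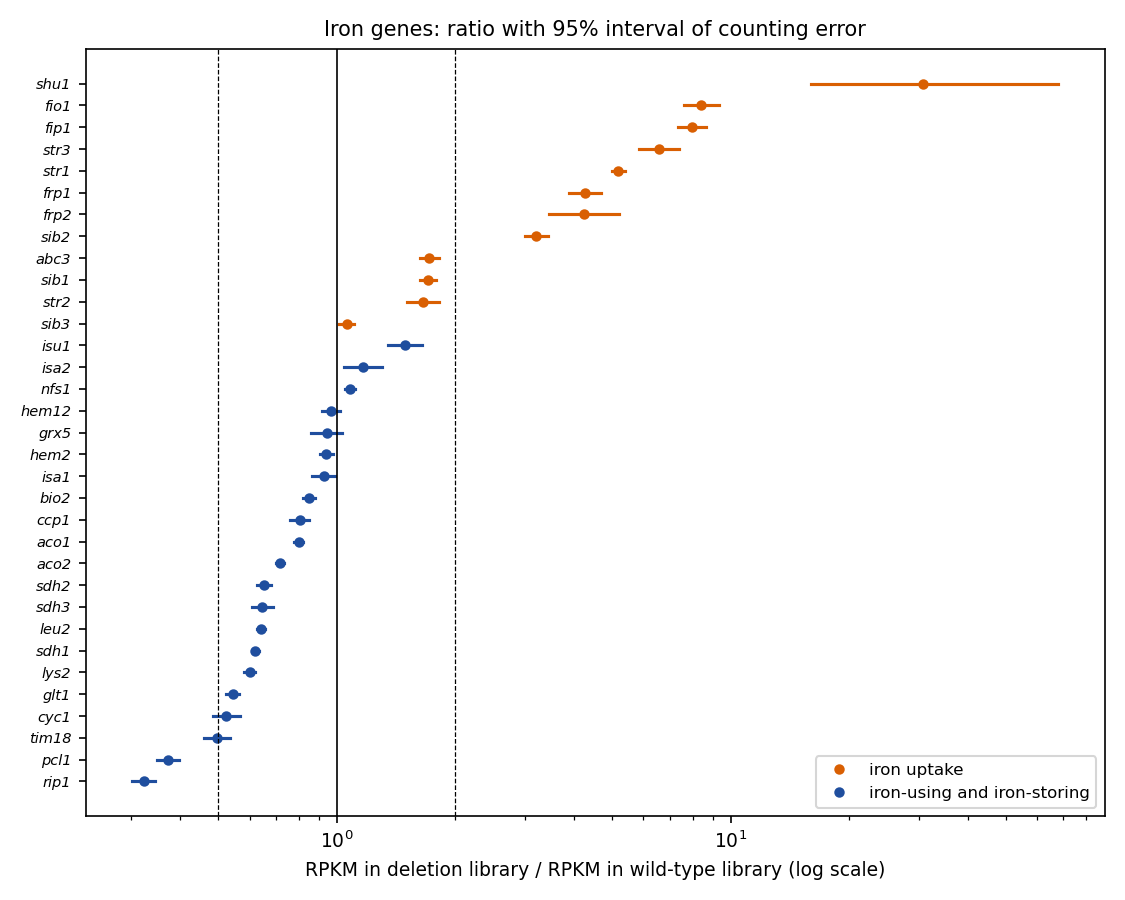
RPKM ratio of deletion to wild type for the 12 iron uptake genes (orange) and the 21 genes listed as iron-using or iron-storing (blue). The scale is logarithmic, with bars for the 95% interval of counting error, a solid line at 1 and dashed lines at 0.5 and 2. The ratios run from 30.7 for shu1 to 0.323 for rip1.

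Nuclear genes of the respiratory chain were lower. Of 22 genes of complexes II, III and IV and cytochrome c, 13 were lower and 9 lay between, and all 22 differences were negative, from −1.62 to −0.53. The median of −1.05 lay at percentile 0. At a mean RPKM of at least 5, the largest differences after rip1 were those of the complex IV subunit genes cox13 (0.343, 0.306 to 0.385) and cox5 (0.374, 0.349 to 0.400) and of the complex III gene qcr8 (0.442, 0.393 to 0.497). Below that level cox7, with 22 reads against 7, had a log2 difference of −1.31; it was chosen after its values were seen.

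Of 16 nuclear genes of ATP synthase, 3 were lower and 13 lay between, with a median of −0.65 at percentile 0. The 3 were atp7 (0.409), atp20 (0.468) and atp4 (0.494), all of the membrane-bound part or its stalk, and atp16 had a log2 difference of −0.85. Not all members are subunits. By annotated product atp10 is an assembly protein (log2 difference −0.07), and atp11 (0.64) and atp12 (−0.001) are F1-ATPase chaperones. Of 17 TCA cycle genes, 1 was lower (tim18, whose protein anchors succinate dehydrogenase) and 16 lay between, with a median of −0.50 at percentile 0. Without genes shared with the respiratory list the median was −0.32 at percentile 0.565. The log2 differences of kgd2 (−0.82), fum1 (−0.76) and idp1 (−0.75) were next in size.

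The machinery of mitochondrial gene expression differed less. None of 67 mitochondrial ribosomal protein genes was higher or lower by the rule, and their median of −0.08 lay at percentile 0.03, with mrpl22 (−0.97), mrpl16 (−0.78), mrpl12 (−0.71) and mrpl38 (−0.69) at the low end. None of 25 other mitochondrial expression factors was higher or lower, and their median of 0.00 (−0.05 after scaling to the median gene) lay at percentile 8.95. In this list the elongation factor gene mef1 had a log2 difference of −0.78, the PPR protein gene ppr8 0.70, cbp6 0.62 and mpa1 −0.50. The 9 mitochondrially encoded genes listed had 102 reads in the wild type and 61 in the deletion, or 5.98 (4.88 to 7.26) against 3.61 (2.76 to 4.64) RPM, reads scaled to the size of the library. None reached a mean RPKM of 1, so none entered the list test. The difference rested largely on SPMIT.06, with 41 reads against 12, a ratio of 0.296 (0.141 to 0.573). Without it the totals were 61 against 49 reads, or 3.58 (2.74 to 4.60) against 2.90 (2.15 to 3.84) RPM, a difference not detectable at this depth. SPMIT.11, with 7 reads against 0 (ratio interval 0 to 0.701), and SPMIT.01, with 33 against 20 (0.333 to 1.10), also had fewer reads in the deletion. SPMIT.04, with 8 against 14, and SPMIT.05, with 0 against 5, went the other way, with ratio intervals that include 1. All SPMIT genes named here were chosen after their values were seen. Whether selection of RNA or unique mapping removed most mitochondrial reads is not given in the sources used here, so these totals do not measure the level of mitochondrial transcripts.

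Cytosolic ribosomal protein genes were lower as a list, although by less than 2-fold. Of 137, 136 had negative differences and only rpl3002 passed the limit (0.463, 0.409 to 0.524). The median was −0.48 at percentile 0, where 95% of random lists lay between −0.32 and −0.19. These random lists were drawn from all genes of like expression, the ribosomal protein genes included, so their range holds part of the same fall. It does not give the level of other genes. Against random lists without matching on expression the median also lay at percentile 0. Log2 differences of rps1602, rpl2302 and rpl102 were −0.87, −0.83 and −0.82.

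Of 18 genes of glycolysis and fermentation, gpd3 was higher and 17 lay between, with a median of 0.36 at percentile 100. The next were pgi1 (0.59), hxk2 (0.50) and eno102 (0.46) on the log2 scale. Of 16 glucose-repressed genes and hexose transporters, 2 were higher and 14 lay between, with a median of 0.35 at percentile 99.4. The 2 were ght5, the high-affinity glucose transporter gene (6.30-fold, 5.96 to 6.65), and the dihydroxyacetone kinase gene dak2 (2.25-fold, 2.06 to 2.47). The malic enzyme gene mae2 had a log2 difference of 0.66 and the invertase gene inv1 0.64. This list no longer stood apart with a pseudocount of 5 RPKM (median 0.20, percentile 94.8) or at a mean RPKM of at least 5 (0.26, percentile 97.49, just under the limit).

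The stress lists stood apart with positive medians, although most of their members lay between the limits. Of 20 core environmental stress genes of the Sty1-Atf1 pathway, 9 were higher and 11 lay between, with a median of 0.78 at percentile 100. After hsp16 and srx1 the largest at a mean RPKM of at least 5 were gst2, a glutathione S-transferase gene (6.28-fold, 6.14 to 6.41), and rds1 (3.76-fold, 3.63 to 3.90). The catalase gene ctt1, a standard member of this response, had a log2 difference of −0.38; it was singled out after its values were seen.

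Of 24 genes of oxidative stress defence, 8 were higher and 16 lay between, with a median of 0.58 at percentile 100; 4 genes are shared with the core stress list. The largest after srx1 and gst2 were the membrane transporter gene caf5 (4.88-fold, 4.54 to 5.24) and the quinone oxidoreductase gene obr1, with a log2 difference of 1.32.

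Of 21 chaperone genes, 4 were higher and 17 lay between, with a median of 0.21 at percentile 99.9. The 4 were hsp16, the Hsp70 gene ssa1 (3.15-fold), the mitochondrial disaggregase gene hsp78 (2.35-fold) and its cytosolic relative hsp104 (2.25-fold). Against random lists that were not matched on expression, the chaperone median was at percentile 97.0.

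Genes with a role in cell death or mitochondrial fission did not stand apart. All 12 lay between, with a median of 0.10 at percentile 67.7. The largest log2 differences were those of cyc1 (−0.93), fis1 (0.61), the Bax inhibitor gene bxi1 (0.56) and trr1 (0.38). The metacaspase gene pca1, chosen after its values were seen, stood at 1.04-fold (0.945 to 1.14). None of 26 genes of autophagy and vacuolar proteolysis was higher or lower by the rule, but 25 differences were positive and the median of 0.36 lay at percentile 99.99. The largest were psp3 (0.93), atg4 (0.82), cpy1 (0.81) and atg1801 (0.64).

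Other nutrient lists gave a mixed picture. Of 10 copper and zinc genes, 1 was higher and 9 lay between, with a median of 0.34 at percentile 99.4; at a mean RPKM of at least 5 the median was 0.21 at percentile 96.1. The 1 was the metallothionein gene zym1, with 2 reads against 16, a ratio of 8.08 (1.90 to 72.4); its mean is below the level for naming and it was chosen after its values were seen. The copper transporter genes ctr6 (0.70) and ctr5 (0.48), the zinc transporter gene zrt1 (0.51) and loz1 (0.48) had positive log2 differences. Of 11 genes listed for phosphate and thiamine, 1 was higher, 1 was lower (pho84, a phosphate transporter gene, 0.437) and 9 lay between. The 1 higher was car1 (3.51-fold), which is annotated as an arginase and so is not a phosphate or thiamine gene. The median of the 11, −0.04, lay at percentile 14.2. It was slightly above 0 when rescaled to TPM or without the 50 most abundant genes. The log2 differences of pho1 and pho7 were −0.70 and 0.65.

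Of 31 genes listed for amino acid synthesis, 1 was higher and 30 lay between, with a median of −0.17 at percentile 16.2; the 1 was the siderophore transporter gene str3. Against random lists without matching on expression the same median lay at percentile 0.11. The log2 differences of met1 and met17 were 0.90 and 0.77. All 18 sterol and low-oxygen genes lay between, with a median of 0.03 at percentile 80.7, which was −0.02 after scaling to the median gene. The largest were erg31 (0.81), sre1 (0.64), hem13 (0.49) and ole1 (0.36).

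Markers of other cell states showed no common direction. Of 33 genes of mating, nitrogen starvation and meiosis, 2 were higher, 1 was lower and 30 lay between, with a median of 0.10 at percentile 38.1. The gene meu10 had a log2 difference of 2.30, spo5, chosen after its values were seen, stood at 3.21-fold (2.08 to 5.10), and the oligopeptide transporter gene isp4 at 0.348 (0.314 to 0.385). The log2 differences of ste11, the regulator of mating, and of isp6 were 0.77 and 0.60. All 10 histone genes lay between, with a median of −0.05 at percentile 89.8, from hhf1 at −0.46 to pht1 at 0.23; hht3 and hht1 were at −0.13 and −0.12. Of 5 Tf2 and subtelomeric helicase genes only 2 could be tested, Tf2-10 with 125 reads against 145 and Tf2-11 with 93 against 68, and both ratio intervals include 1. Near-identical copies make these values uncertain.

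**Figure D3:**
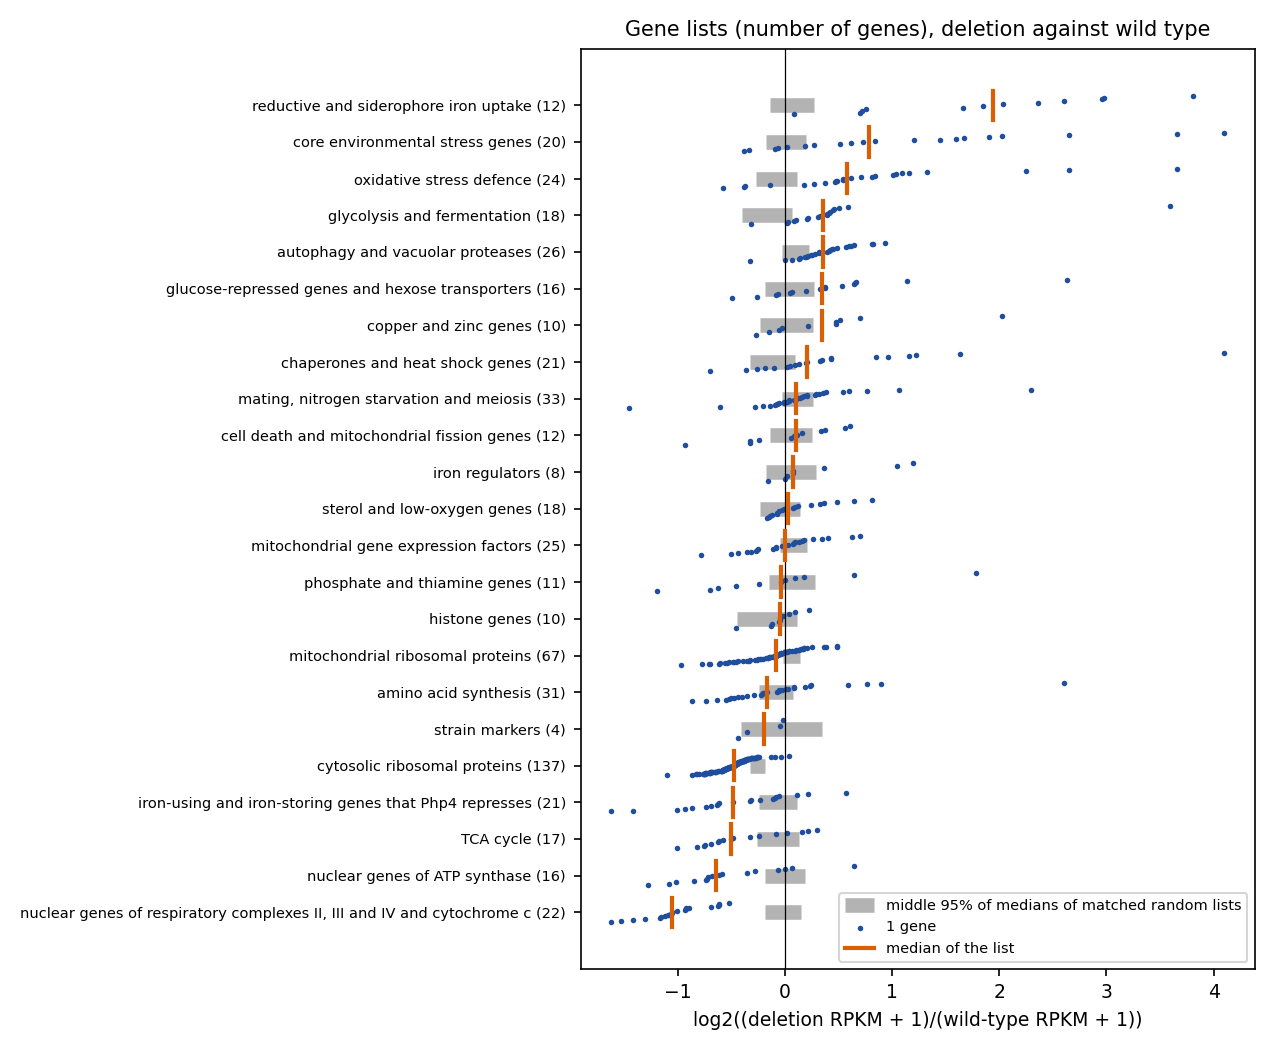
Log2 differences between deletion and wild type on the RPKM + 1 scale for the members of each gene list (blue points), with the median of the list (orange line) and the middle 95% of the medians of random lists matched on expression (grey bar). The medians run from −1.05 for the respiratory complexes to 1.94 for iron uptake.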

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

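The 3 alternatives chosen after seeing the data were lists without members of another function, lists without members of the respiratory complex list, and random lists drawn without cytosolic ribosomal protein genes; the others were planned. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. At a pseudocount of 5 RPKM, 103 genes were higher and 37 lower, the latter all among the 57; fewer weakly expressed genes reach the limit by construction. By construction too, a limit of 1.5-fold gave 396 higher and 224 lower genes and one of 4-fold gave 33 and 6. The other alternatives gave 127 to 157 higher and 48 to 69 lower genes. The log2 difference of ppr10 was −6.99 at a pseudocount of 0.1 RPKM and −3.80 at 5, since its level in the deletion was only 0.459 RPKM. Over 23 lists there were 216 alternative values: 210 stayed on the same side of the percentile limits, 5 no longer stood apart, 1 did so newly and 0 reversed. The 5 were the iron-using list without respiratory members (−0.24), the glucose-repressed list at a pseudocount of 5 RPKM (0.20) and at a mean RPKM of at least 5 (0.26), the copper and zinc list at that mean (0.21), and chaperones against unmatched random lists (0.21). The new one was amino acid synthesis against unmatched random lists (−0.17). The cause was not tested. Depth limits 15 of the higher or lower genes, which had under 50 reads in both libraries together.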

Other observations

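Tests chosen only after the result was seen were the gene groups of the next paragraph, which were picked because some members stood out, the shares at single chromosome ends, the comparison with mitochondrial ribosomal proteins, the glucose-repressed list as a measure of growth state, the iron-using list without respiratory members, and the count of neighbouring pairs.

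Surface glycoproteins of flocculation differed in both directions. Of 9 pfl and gsf2 genes, 4 were higher and 2 were lower: pfl9, gsf2, pfl8 (3.30-fold) and pfl6 (3.41-fold, 2.14 to 5.62) against pfl2 (0.449, 0.435 to 0.463) and pfl7 (0.189, 0.117 to 0.294). The group's median log2 difference was 0.45. Of 5 genes with aldo/keto reductase in the product name 4 were higher, among them SPBC215.11c (5.19-fold) and SPAC750.01 (3.26-fold), with a median of 1.29. By product name, 4 genes were alcohol or short chain dehydrogenases, and 2 were higher (adh8 and SPCC663.08c), both already among the largest differences. In the same group adh1, the main fermentation enzyme gene, stood at 1.31-fold and adh4 at 0.803. This choice by name missed osr1 (20.6-fold), annotated only as a dehydrogenase. Among 44 genes with proteasome in the product name, assembly factors included, none passed the 2-fold limit, and the median was 0.22. The wtf genes, a family of meiotic drivers whose similar copies make values uncertain, had 3 of 20 higher (wtf18, wtf19 and wtf20) and a median of 0.49. The 3 galactose genes went both ways: gal10 was higher at 2.48-fold (2.10 to 2.93), gal7 stood at 1.97-fold and gal1 at 0.623 (0.559 to 0.693).

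Near ppr10, the gene cys2, which encodes homoserine O-acetyltransferase and lies 2 places away, stood at 3.21-fold (3.09 to 3.34), while the genes on either side of ppr10, rpl2501 and exo70, had log2 differences of −0.55 and −0.42. The 12 reads of ppr10 in the deletion library covered 69.8% of its coding length by the deposited score. Neighbouring genes were 2-fold higher or lower the same way in 28 pairs, against a mean of 4.38 and at most 13 in 10000 shuffled gene orders. Without the genes at chromosome ends there were 18 such pairs, against a mean of 3.12. Shuffling does not account for reads shared by neighbours. The pairs include sro1 with its copy SPBC1347.14c, and wtf19 with wtf20, of a family with similar copies. They also include fip1 with fio1 (log2 differences 2.95 and 2.98) and osr1 with SPCC663.08c (4.32 and 3.20), genes without a near-identical copy. Without a stated strand setting, overlapping neighbours may share reads too.

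The lower level of nuclear respiratory genes was set against biases of the assay. The 22 genes have a median coding length of 452 bases against 1152 in all genes. After the trend with length was removed their median log2 difference was still −0.999, and after removal of the trend with GC content it was −1.11. The uncorrected median of −1.05 lay at percentile 0 among random lists matched on length, and also among those matched on GC content. An equal fall of all nuclear genes for mitochondrial proteins is argued against by the mitochondrial ribosomal proteins, whose median lay 0.97 above that of the respiratory list. The lower level was not confined to that list. The median of ATP synthase genes was −0.65, and that of TCA cycle genes without respiratory members was −0.32 at percentile 0.565. Loss of ppr10 may lower the respiratory transcripts, but each genotype is 1 culture and 1 library. A difference between cultures or preparations therefore stays open, and was not tested.

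Among the 40 outermost protein-coding genes at each of 6 ends, 177 could be tested and 39 (22.0%) were 2-fold higher or lower, against 3.24% elsewhere; 21 were higher, shu1 and str3 among them, and 18 lower. Taken singly, each end lay above its matched range except the left end of chromosome III, with 4 of 39 (10.3%, matched range 0% to 10.3%), while the left end of chromosome I had 9 of 26 (34.6%). For the ends together, low read numbers are argued against by random genes of like expression, of which 3.95% to 11.3% passed in 95% of draws, and shared reads by the 21.6% that passed without near-identical copies (matched range 3.09% to 10.5%). Complete loss of DNA at the ends is argued against by the lower genes, of which 1 of 18 had an interval reaching down to the ratio of ppr10. A difference in silencing between the strains, partial loss or rearrangement of an end, or a difference in strain background may remain, and these were not tested.

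The higher iron uptake genes were set against shared reads and growth state. None of them has a near-identical copy (0 of 12), which argues against reads moved between copies. A deletion culture further on in growth, with less glucose, predicted a large difference in the glucose-repressed list, whose median was 0.35: above matched random lists, but below a difference of 1, so this explanation cannot be told apart from genotype. Lower iron in the deletion cells is a hypothesis that these libraries could hold as well, and it was not tested. The gene php4 was higher, but whether it changed independently of the uptake genes cannot be told from these libraries. The iron-using genes add no separate support: without members of the respiratory list their median was −0.24, inside the matched range of −0.25 to 0.17. Cellular iron was not measured in the data used here.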
